A study of Mus musculus with 2 samples.

How the data were processed

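Gene expression was measured by droplet-based single-cell RNA sequencing in 2 libraries, each from the hindlimb of 1 mouse embryo of the FVB strain at embryonic day 11.5. Per the labels' protocols, cells were dissociated with collagenase II, 10000 cells were loaded on a 10x Genomics 3' v3.1 chip, and about 50000 reads per cell were sequenced on an Illumina NovaSeq instrument. Each group (dual-enSERT-1 and dual-enSERT-2) held 1 library, so differences have no replicate check and no test was run across libraries or cells.

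The deposited matrices hold whole-number UMI counts per gene and barcode, not normalized, per the file headers. The headers name Cell Ranger 7.0.1, whereas the submitters' processing notes name Cell Ranger 3.1.0, Seurat 4 and the genome build mm39, and which version made the counts was not settled. The annotation release and the use of intronic reads and of strand are not given in the sources used here, so reads of overlapping or antisense genes cannot be assigned with certainty. Both feature lists hold eGFP and mCherry as features of their own. Of the 56982 feature IDs, 56236 were found in GENCODE M39 on GRCm39, from which the printed coordinates were taken. Features sharing a symbol were kept apart by ID, and Aldoa, whose symbol belongs to 2 features, was left out of its gene list.

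Computation used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, Scanpy 1.11.5, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. Barcodes with at least 1000 genes and at most 10% mitochondrial UMIs were kept, which removed 2593 barcodes of dual-enSERT-1 and 1502 of dual-enSERT-2 by genes, and a further 125 and 700 by mitochondrial share. Scrublet (expected rate 8%) then removed 1709 doublets (9.61%) and 229 doublets (3.43%). Cells of each library were clustered separately without eGFP, mCherry and Shh. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 nearest neighbours and Leiden resolution 1 were used. Clusters were named from fixed marker lists where at least 3 markers of a class were at least 2-fold higher than in the other cells and seen in at least 10% of the cluster. For mesenchyme the comparison was with the cells of the other named classes. A cluster whose median UMI count was under 1/3 of its library's, with no marker of its class among its 10 leading genes, stayed unnamed. The apical ectodermal ridge was read with the ectoderm. No cluster was named megakaryocyte, neural crest and glia, neuron, perivascular or melanocyte.

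Levels are CPM, computed from the deposited counts as the UMIs of a gene over all UMIs, pooled over the cells of a class, with exact Poisson intervals, and ratios and shares have exact Clopper-Pearson intervals, all at 95%. These intervals cover counting error only. Shares of cells with a UMI were read after thinning each cell to 5000 UMIs, the largest of 2000, 5000 and 10000 UMIs that at least 80% of kept cells reached in both libraries, and shallower cells were left out. The anterior-posterior index of a thinned cell is the number of posterior genes with a UMI (Hand2, Hoxd11, Hoxd12, Tbx2) minus the number of anterior genes with a UMI (4 genes, among them Pax9, Alx1 and Alx4). Some genes of the index, the lists and the naming rule are not reported here. An index of -1 or lower was called anterior, 1 or higher posterior and 0 middle. Distal cells were those with a Hoxa13 or Hoxd13 UMI. The background fixed at the start was the level in erythroid-, endothelial- and macrophage-like cells. Because macrophage-like cells and 1 erythroid-like cell per library carried far more reporter than the rest, ectoderm-, endothelial- and muscle-like cells were taken instead, after the data were seen. Both backgrounds are printed, and a background without endothelial-like cells was added later.

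The classes, contrasts, index, marker lists, gene lists and most alternative settings were fixed before the data were examined. Folds are log2 ratios of pooled CPM with a pseudocount of 1 CPM. Named in each contrast of cell groups were up to 12 genes per direction with at least 20 CPM in either cell group in both libraries and the same direction in both, ranked by the smaller absolute log2 fold, which had to reach 0.58. Index genes were left out of the anterior-posterior ranking. Between libraries the rule took the 12 largest folds per direction, with at least 20 CPM in either library and an absolute log2 fold of at least 1. Always named were eGFP, mCherry, Shh, Ptch1, Gli1, Hand2, Hoxd13, Lmbr1, Eif4enif1 and Drg1. The 17 gene lists covered Shh response, posterior, anterior, proximal, distal, FGF response, ETS factors, BMP response, WNT response, cartilage, connective tissue, hindlimb, dissociation stress, hypoxia, mitosis, sex-linked genes and the neighbours of the H11 insertion site. A member counted as measured at 5 CPM or more, and each list's median was placed among 10000 random lists of the same size matched on mean expression.

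The contrast computation was tested on simulated counts drawn from the dual-enSERT-2 mesenchyme-like cells split into 2 equal sets. Over 56982 genes it recovered 100 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, with 0 false calls. Both simulated libraries were drawn from the same pooled profile with Poisson error only. The sets were also larger than the smaller cell groups compared, such as the 237 cells with eGFP alone in dual-enSERT-2. The test therefore checks the computation and not the effect of variation between cells or embryos. The alternatives were a minimum of 2000 genes, doublets kept, Leiden resolution 0.5, all kept cells, no thinning, detection at 2 UMIs, a wider index gap, mean per-cell CPM, Shh detected at 2 UMIs, median-ratio scaling and at most 5% mitochondrial UMIs. Inclusion of the shallow unnamed clusters and subtraction of the background, with and without endothelial-like cells, were added after seeing the data.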

Results

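The data are single-cell transcriptomes of mouse hindlimbs at E11.5 from 2 transgenic embryos that carried a pair of fluorescent reporters at H11, a transgene insertion site on chromosome 11 near Eif4enif1 and Drg1. Each reporter was driven by the ZRS, the limb enhancer of Shh that lies in an intron of Lmbr1. The reference ZRS drove mCherry and the ZRS404G>A allele, named for its base substitution, drove eGFP. The libraries, dual-enSERT-1 and dual-enSERT-2, differ in the arrangement of the construct. Only the label of dual-enSERT-2 names parts called B, at both ends, and SI, between the reporters. What these parts are is not spelled out, and the label of dual-enSERT-1 has neither. The libraries also differ in embryo and preparation, and these differences cannot be told apart. Shh lies on mm39 chromosome 5 from 28661813 to 28672254 on the minus strand, and Lmbr1 from 29434800 to 29583510. The question was in which limb cells each enhancer allele was active.

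The dual-enSERT-1 library held 20508 barcodes, above the 10000 cells loaded per the labels, and 298653282 UMIs, and dual-enSERT-2 held 8885 barcodes and 184301053 UMIs. After filtering, 16081 and 6454 cells remained, with medians of 14008 and 25802 UMIs and of 4525 and 5458.5 genes.

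Limb mesenchyme, the tissue that forms skeleton and connective tissue, made up most cells in both libraries. It was 81.6% of dual-enSERT-1 (95% interval 80.9 to 82.2, 13115 cells) and 58.7% of dual-enSERT-2 (57.5 to 59.9, 3789 cells). Erythroid-like cells made up 1.52% (1.33 to 1.72) and 25.3% (24.3 to 26.4). Muscle-like cells were 3.45% and 1.19%, ectoderm-like cells 2.67% and 2.77%, endothelial-like cells 1.27% and 0.930%, and macrophage-like cells 0.398% and 0.806%. Shallow clusters that stayed unnamed held 9.13% (1468 cells, median 2983.5 UMIs) and 10.3% (662 cells, median 5048.5 UMIs). Under a minimum of 2000 genes the unnamed share was 1.08% and 5.01%, and the erythroid-like share of dual-enSERT-1 was 0.836%.

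Both reporters were higher in mesenchyme-like cells than in the ectoderm-, endothelial- and muscle-like cells pooled as background. In dual-enSERT-1 eGFP stood at 146 CPM (144 to 148) in mesenchyme against 34.3 CPM in the background, and mCherry at 54.2 CPM against 9.34 CPM. In dual-enSERT-2 eGFP stood at 27.1 CPM (26.1 to 28.1) against 7.98 CPM, and mCherry at 21.4 CPM against 8.34 CPM. Endogenous Shh was 7.54 CPM (7.16 to 7.92) and 8.04 CPM (7.51 to 8.60). There were 2.70 eGFP UMIs per mCherry UMI in dual-enSERT-1 (2.64 to 2.76) and 1.26 in dual-enSERT-2 (1.196 to 1.34). No library carried the same ZRS allele on both reporters, so these ratios are not calibrated. In the erythroid-, endothelial- and macrophage-like cells named as background at the start, eGFP was 36.4 and 7.998 CPM and mCherry 32.1 and 7.65 CPM, with median depths of 19409 and 27179 UMIs. A single cell per library weighed on the erythroid-like level of mCherry, which was 26.1 and 5.25 CPM with it and 8.43 and 2.74 CPM without it. The eGFP to mCherry ratio of dual-enSERT-1 was alike in ectoderm-like (3.79), endothelial-like (3.52) and muscle-like cells (3.70), but in dual-enSERT-2 eGFP ranged from 1.08 CPM in ectoderm-like to 15.6 CPM in endothelial-like cells. The 60 endothelial-like cells of dual-enSERT-2 held 19.1 CPM of mCherry (13.8 to 25.8), an interval that includes the mesenchyme level. Without endothelial-like cells, a background added after the data were seen, the levels of dual-enSERT-2 were 5.15 CPM of eGFP and 4.32 CPM of mCherry (2.82 to 6.33), and those of dual-enSERT-1 35.0 and 9.39 CPM.

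At 5000 UMIs per cell, eGFP was detected in 26.0% of dual-enSERT-1 mesenchyme-like cells (25.2 to 26.7) and mCherry in 9.83% (9.32 to 10.4). The background shares were 14.9% and 3.72%. In dual-enSERT-2 eGFP was detected in 8.16% (7.31 to 9.09) and mCherry in 6.88% (6.09 to 7.74), against 1.76% and 2.82% in the background. In the background named at the start the shares were 17.2% and 7.86% in dual-enSERT-1 and 2.02% and 1.38% in dual-enSERT-2. Too shallow to be thinned were 111 and 41 mesenchyme-like cells, 221 and 32 background cells, and 42 and 11 cells of the background named at the start. Median depths before thinning were 14582 and 27322 UMIs in mesenchyme and 16036 and 21461 UMIs in the background. Without thinning the mesenchyme shares were 47.2% and 19.4% in dual-enSERT-1, where the background shares were 40.2% and 14.6%, and 28.0% and 22.8% in dual-enSERT-2, where they were 10.1% and 10.4%. With detection at 2 UMIs the mesenchyme shares were 11.02% for eGFP and 3.58% for mCherry in dual-enSERT-1, with 1.44% and 0.206% in the background, and 1.89% and 1.73% in dual-enSERT-2, with 0% (0 to 1.29) and 0.352% in the background.

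Most cells with eGFP had no mCherry UMI at this depth. In dual-enSERT-1 20.8% of mesenchyme-like cells had eGFP alone, 4.61% mCherry alone and 5.22% both, and 2.55% would have both if the reporters were independent. In dual-enSERT-2 these shares were 6.32%, 5.04%, 1.84% and 0.562%. Of eGFP-detected cells, 79.9% (78.5 to 81.2) and 77.5% (72.4 to 82.0) lacked mCherry. Of mCherry-detected cells, 46.9% (44.1 to 49.65) and 73.3% (67.4 to 78.6) lacked eGFP. In the background 14.3% (12.2 to 16.7) and 1.41% (0.385 to 3.57) of cells had eGFP alone.

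The next comparison was between mesenchyme-like cells with eGFP alone and cells with mCherry (2699 against 1278 cells in dual-enSERT-1, 237 against 258 in dual-enSERT-2). As 14.3% of background cells of dual-enSERT-1 also had eGFP alone, this group may hold many cells with eGFP at the background level. It may also hold cells whose mCherry went undetected at this depth. Shh itself was lower in the eGFP-alone cells, at 4.76 against 49.0 CPM in dual-enSERT-1 (log2 fold -3.12) and 26.3 against 47.9 CPM in dual-enSERT-2 (-0.84). Bmp4, a signalling ligand, was lower at -0.92 and -0.71, and Ankrd6, a modulator of Wnt signalling, at -0.65 and -0.78. Higher in the eGFP-alone cells of both libraries were Grem1, a secreted BMP antagonist (0.83 and 0.72), and Boc, a Hedgehog co-receptor (0.63 and 0.87). So were the axon guidance ligand Sema3a (0.75 and 0.70), the adhesion molecules Lsamp (0.68 and 1.01) and Cntn4 (0.64 and 1.11), the laminin chain Lama2 (0.86 and 0.69) and the glypican Gpc5 (0.82 and 0.62). The proximal limb transcription factor Zbtb16 (0.70 and 0.65), Dpyd of pyrimidine breakdown (0.69 and 0.89), Itm2a (0.64 and 0.71), Asb4 (0.61 and 0.63) and the collagen gene Col1a2 (0.69 and 0.61) completed the 12 genes taken by the naming rule. With detection at 2 UMIs the dual-enSERT-2 folds of Lsamp (-0.51), Boc (-0.013) and Asb4 (-0.095) were below 0, as was that of Cntn4 (-0.013) without thinning.

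Among the gene lists, all 6 measured proximal genes were higher in eGFP-alone cells of both libraries, with medians of 0.50 and 0.15 (percentiles 100 and 99.9), among them Meis1 (0.61 and 0.25) and Meis2 (0.59 and 0.33). All 4 measured anterior genes were higher, with medians of 0.26 and 0.27 (percentile 99.9 in both), led by Asb4. Of 7 posterior genes 6 were lower, with medians of -0.21 and -0.35 (percentile 0 in both), among them Tbx2 (-1.27 and -0.35) and Hoxd13 (-0.28 and -0.83). Of 8 distal genes 5 were lower, with Hoxa13 at -0.51 and -0.72. Of 10 BMP response genes 7 were lower, with Bambi at -0.86 and -0.57, and of 10 Shh response genes 5 were lower and 2 higher, Ptch1 standing at -0.13 and -0.10 and Gli1 at 0.05 and -0.15. Hand2 was -0.20 and -0.35. With detection at 2 UMIs Hoxd13 was 0.16 in dual-enSERT-1 and Hand2 0.033 in dual-enSERT-2. Lmbr1 was -0.37 and 0.04, Drg1 -0.12 and 0.05, and Eif4enif1 -0.49 and 0.00.

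Along the anterior-posterior axis both reporters were lower in cells with an anterior profile (690 and 246 cells) than in cells with a posterior profile (8741 and 2409 cells). In dual-enSERT-1 anterior eGFP was 87.5 CPM against 178 CPM posterior, a ratio of 0.492 (0.460 to 0.524), and anterior mCherry was 13.7 against 71.7 CPM, a ratio of 0.191 (0.162 to 0.224). In dual-enSERT-2 eGFP was 12.2 against 35.1 CPM, a ratio of 0.347 (0.276 to 0.432), and mCherry 7.78 against 28.6 CPM, a ratio of 0.272 (0.203 to 0.357). Anterior eGFP was 2.55 times the background level in dual-enSERT-1 and 1.53 times in dual-enSERT-2, and anterior mCherry was 1.47 and 0.932 times. Against the background named at the start anterior mCherry was 0.426 and 1.02 times, and against the background without endothelial-like cells 1.46 and 1.80 times. Anterior eGFP was 2.40 and 1.52 times the background named at the start. Against the background without endothelial-like cells it was 2.50 and 2.36 times. In dual-enSERT-2 that background held only 31 eGFP UMIs (5.15 CPM, 3.50 to 7.31). Its muscle-like cells stood at 11.6 CPM (7.67 to 16.9), an interval that includes the anterior level, so the 2.36 depends on the classes pooled. Among distal cells of the anterior profile, eGFP reached 137 CPM and mCherry 28.8 CPM in dual-enSERT-1 (190 cells), and 11.4 and 10.5 CPM in dual-enSERT-2 (38 cells). The other 500 anterior cells of dual-enSERT-1 held 64.3 CPM of eGFP (58.7 to 70.3), 1.87 times the background, and 6.69 CPM of mCherry, 0.716 times the background. In dual-enSERT-2 the other 208 anterior cells held 12.3 CPM of eGFP (9.62 to 15.5) and 7.29 CPM of mCherry, 1.54 and 0.873 times the background. Distal cells made up 4856 of the posterior cells in dual-enSERT-1 and 1132 in dual-enSERT-2. Within distal cells the anterior to posterior ratios were 0.534 for eGFP and 0.265 for mCherry in dual-enSERT-1, and 0.208 (0.108 to 0.365) and 0.231 (0.115 to 0.414) in dual-enSERT-2. The index is a range and not a cell type. In dual-enSERT-1 619 cells had an index of -1, 3573 of 0 and 3580 of 1, and in dual-enSERT-2 221, 1093 and 1343 cells. With the background subtracted the anterior to posterior ratio of dual-enSERT-1 was 0.370 for eGFP and 0.0699 for mCherry, and that of eGFP in dual-enSERT-2 was 0.155. Subtracted ratios have no interval here. The 0.155 is uncertain, as anterior eGFP (9.70 to 15.1 CPM) and its background (6.17 to 10.2 CPM) overlapped in dual-enSERT-2. Without endothelial-like cells in the background the ratios of dual-enSERT-2 were 0.235 for eGFP and 0.142 for mCherry. With an index of -2 or lower against 2 or higher, the mCherry ratio of dual-enSERT-1 was 0.109, and the ratios of dual-enSERT-2 were 0.271 for eGFP (0.124 to 0.516) and 0.299 for mCherry (0.129 to 0.590).

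**Figure D1:**
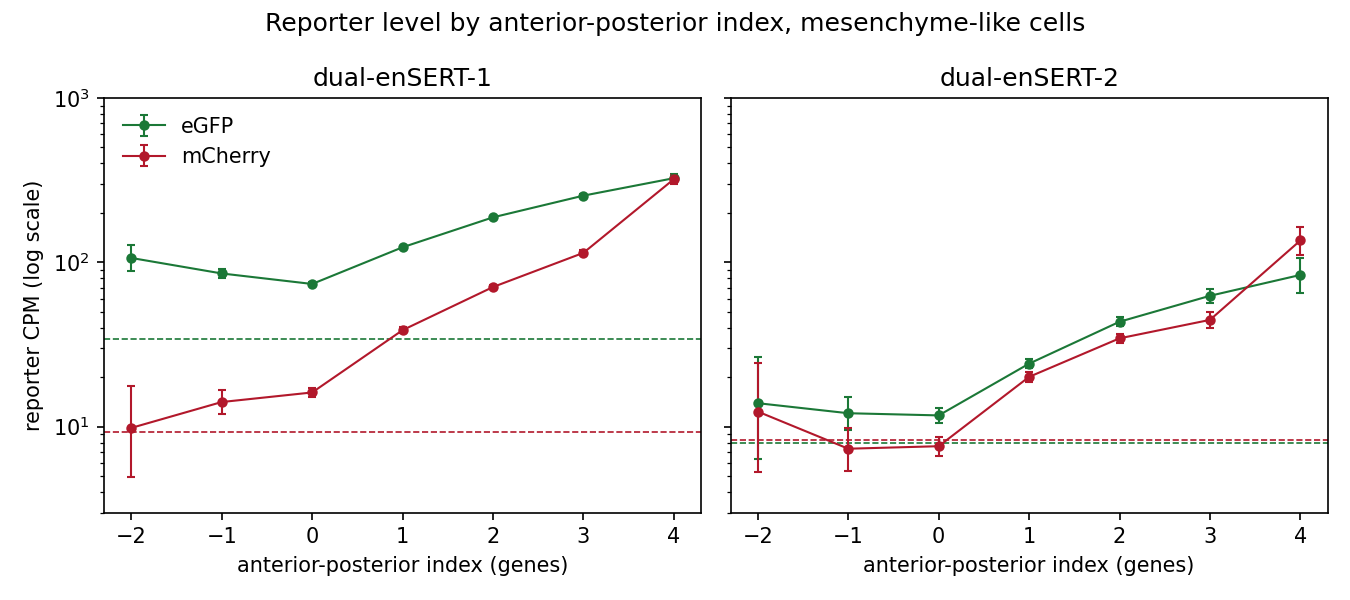
Reporter CPM on a log axis against the anterior-posterior index (number of posterior minus anterior genes detected) in mesenchyme-like cells of each library; points are pooled levels for index values with at least 20 cells, bars 95% Poisson intervals, and dashed lines the level in ectoderm-, endothelial- and muscle-like cells. At an index of 0, eGFP of dual-enSERT-1 stands at 73.8 CPM, above its background of 34.3 CPM, and that of dual-enSERT-2 at 11.7 CPM.

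Among genes outside the index with the same direction in both libraries, lower in anterior cells were Hoxd13, a regulator of digit formation (-3.50 and -3.83), the Hedgehog receptor and target Ptch1 (-2.36 and -2.08) and the Hedgehog-activated transcription factor Gli1 (-2.22 and -2.21). Shh was 0.274 against 10.5 CPM (ratio 0.0260, 0.00536 to 0.0762) and 0.293 against 11.9 CPM (ratio 0.0246, 0.00298 to 0.0892). The noncoding genes Hand2os1 (-4.001 and -4.14) and Tbx3os1 (-2.41 and -3.17), named for the neighbouring genes Hand2 and Tbx3, were lower too. So were Dlk1, a Notch pathway ligand (-2.87 and -3.60), Rspo3, which potentiates Wnt signalling (-2.32 and -2.28), the ErbB ligand Nrg1, feature ENSMUSG00000062991 (-2.65 and -2.25), the protease gene Adamts17 (-2.39 and -2.11), Hdnr (-2.88 and -2.09) and the collagen gene Col23a1 (-1.76 and -1.81). Higher in anterior cells were Kctd8 (2.98 and 2.81), the adhesion genes Pcdh17 (2.07 and 2.14), Pcdh19 (2.16 and 1.74), Cntn4 (2.53 and 1.88) and Lsamp (1.51 and 1.55), and the BMP-responsive homeobox gene Msx2 (1.75 and 2.03). Also higher were the peptidase Mme (2.02 and 1.70), the microtubule-binding Dcx (1.67 and 2.07), heparanase 2, Hpse2 (1.84 and 1.60), Asb4 (1.62 and 1.59), the dynein chain Dync1i1 (1.53 and 1.80) and E130114P18Rik (1.34 and 1.82).

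All 10 measured Shh response genes were lower in anterior cells, with medians of -2.18 and -2.10 (percentile 0 in both), among them Hhip (-2.51 and -1.78) and Tbx2, which is also part of the index. Of 8 posterior genes 7 were lower and all 7 anterior genes were higher, which the index partly sets. Outside the index, Osr1 was -1.85 and -1.58 and Gli3 0.77 and 0.77. Of 10 BMP response genes 7 were higher, with medians of 0.30 and 0.26 (percentile 100 in both), Msx1 standing at 1.23 and 1.21. Of 9 distal genes 5 were lower and 3 higher, with Hoxa13 at -1.64 and -1.77 and Lhx9 at 1.57 and 1.26. Of 5 connective tissue genes 3 were lower, among them Osr2 (-0.69 and -1.87). Of 5 hindlimb genes 3 were higher, and Hoxc11 was lower (-0.93 and -1.30). Of 5 dissociation stress genes 4 were lower, with Jun at -0.84 and -0.52. Hand2, an index gene, stood at -3.67 and -3.37, Lmbr1 at 0.15 and 0.06, Drg1 at -0.13 and -0.02, and Eif4enif1 at -0.51 and 0.02.

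Because the ZRS controls Shh in the limb, reporter levels were compared between mesenchyme-like cells with and without a Shh UMI (579 against 12536 cells in dual-enSERT-1, 240 against 3549 in dual-enSERT-2). In dual-enSERT-1 mCherry was 22.6-fold higher in Shh-detected cells (21.8 to 23.5), at 569 against 25.2 CPM, and eGFP was 3.23-fold higher (3.13 to 3.33), at 421 against 131 CPM. In dual-enSERT-2 the folds of mCherry, 11.98 (11.03 to 13.01), and of eGFP, 11.4 (10.6 to 12.3), overlapped within counting error. Their levels were 143 against 11.96 CPM and 176 against 15.5 CPM. Within distal cells the folds were 13.9 for mCherry and 1.96 for eGFP in dual-enSERT-1, and 8.59 and 8.72 in dual-enSERT-2. In distal cells without a Shh UMI, eGFP was 218 CPM and mCherry 42.1 CPM in dual-enSERT-1, and 22.0 and 18.1 CPM in dual-enSERT-2. Outside the distal cells, without Shh, mCherry was 8.29 and 8.47 CPM, and eGFP 44.0 and 11.7 CPM. This mCherry level was 0.888 and 1.01 times the background, and 0.883 and 1.96 times the background without endothelial-like cells. Shh was sparse, so some Shh-expressing cells stand among those without a UMI. With the background subtracted, the dual-enSERT-1 folds were 35.4 for mCherry and 4.02 for eGFP, and those of dual-enSERT-2 37.3 and 22.5. The dual-enSERT-2 folds have no interval and divide by only 3.62 and 7.50 CPM left in cells without Shh. With endothelial-like cells left out of the background the folds were 35.5 and 4.04 in dual-enSERT-1, and 18.2 and 16.6 in dual-enSERT-2.

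**Figure D2:**
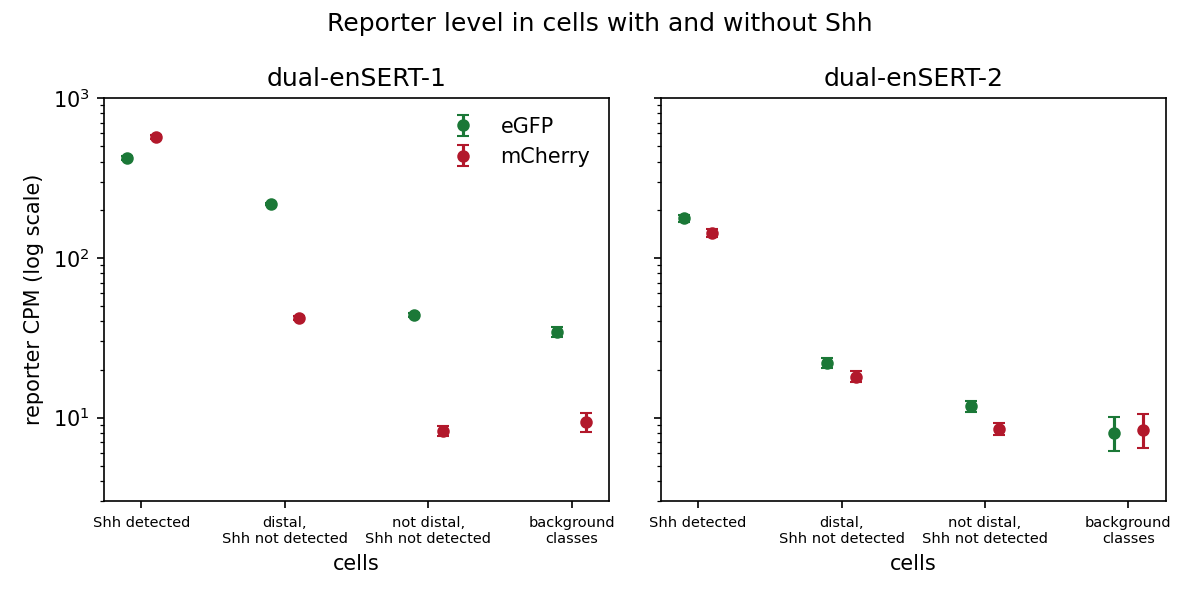
Reporter CPM on a log axis in Shh-detected mesenchyme-like cells, in distal and other mesenchyme-like cells without a Shh UMI, and in background cells (ectoderm-, endothelial- and muscle-like), with 95% Poisson intervals. In distal cells without Shh the reporters stand at 218 and 42.1 CPM in dual-enSERT-1 and at 22.0 and 18.1 CPM in dual-enSERT-2.

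Among genes with the same direction in both libraries, Cck stood highest in Shh-detected cells, which encodes the peptide cholecystokinin (log2 fold 5.14 and 4.07). The transcription factors Prdm1 (2.58 and 2.65), Tbx2 (2.53 and 2.64) and Tbx3 (1.71 and 1.73) and the ligand Bmp4 (2.03 and 2.61) were higher. So were Sgcz, a sarcoglycan (2.22 and 2.37), Adamts17 (1.84 and 2.24), the laminin chain Lama1 (1.67 and 1.58), Nkain3 (1.52 and 1.63) and the adhesion molecule Kirrel3 (1.52 and 2.61). The reporters were on the same list, mCherry at 4.45 and 3.48 and eGFP at 1.68 and 3.43. Lower were the kinase gene Nrk (-3.16 and -2.91), the chemokine Cxcl12 (-2.90 and -3.00), Col1a2 (-2.46 and -2.84), Hpse2 (-2.44 and -2.76), Boc (-2.49 and -2.42) and Asb4 (-2.18 and -2.83). The chondrogenic regulator Sox9 (-2.29 and -2.15), the BMP antagonist Grem1 (-2.08 and -2.27), the matrix protein gene Smoc1 (-2.18 and -2.05), Cntn4 (-2.01 and -2.36) and Eya4 (-2.23 and -1.98) were lower as well.

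**Figure D3:**
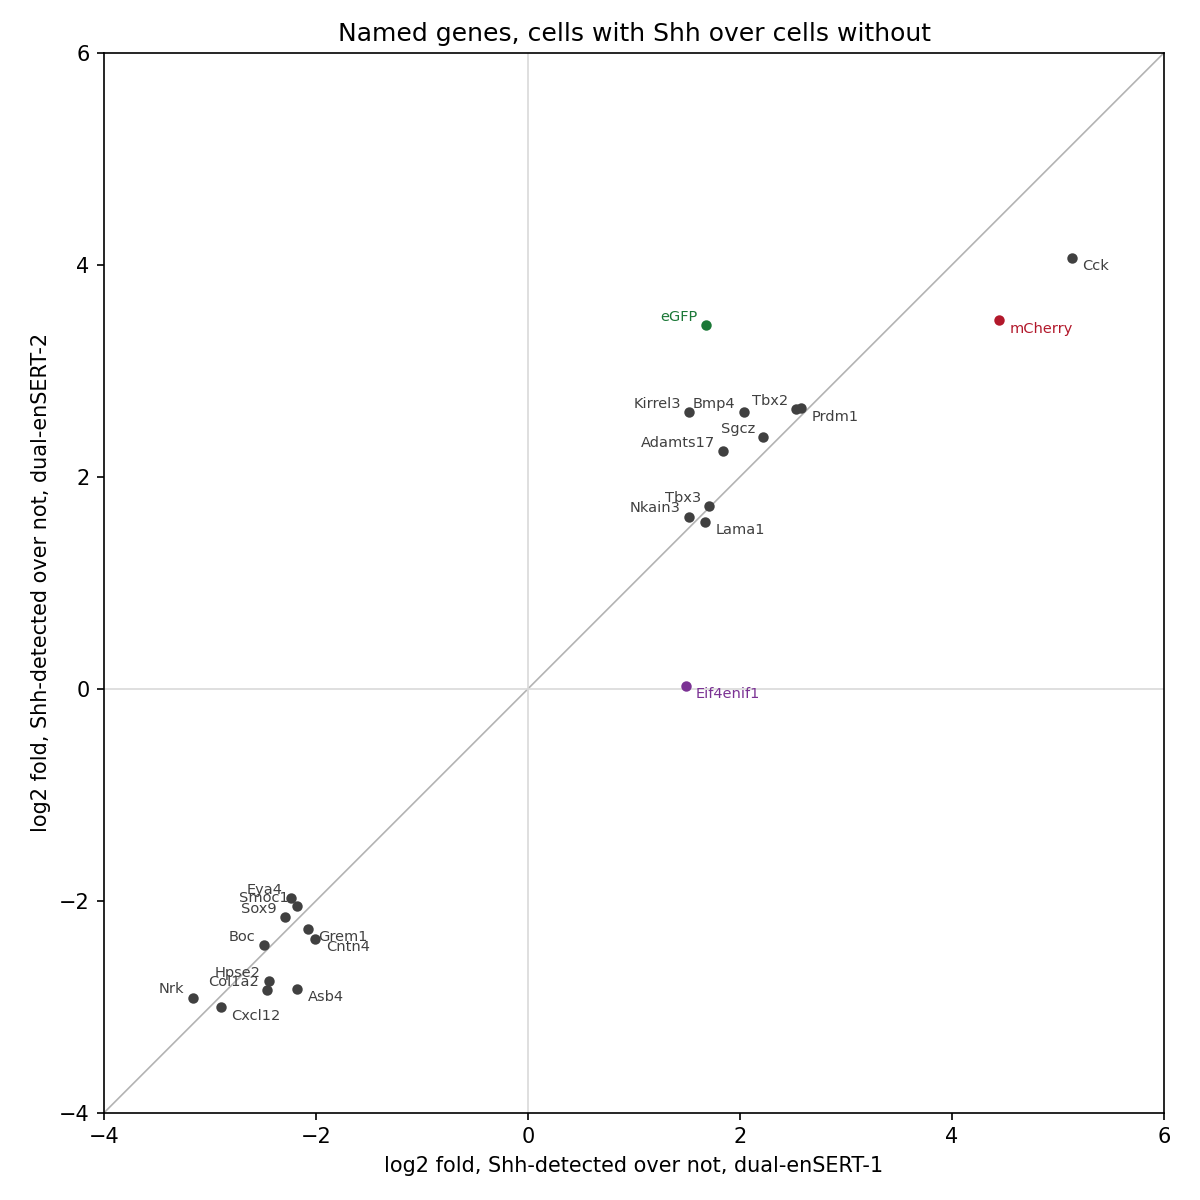
Log2 folds between Shh-detected and other mesenchyme-like cells in dual-enSERT-1 (x axis) and dual-enSERT-2 (y axis) for genes taken by the naming rule and for Eif4enif1; the diagonal marks equal folds. The reporter eGFP lies at 1.68 and 3.43, mCherry at 4.45 and 3.48, and Eif4enif1 at 1.49 and 0.03.

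Of 10 measured Shh response genes 7 were higher and 2 lower in Shh-detected cells, with medians of 0.34 and 0.77 (percentile 100 in both). Ptch1 stood at 0.59 and 0.96, Gli1 at -0.24 and 0.24, and Hhip, a Hedgehog-binding protein, at -0.72 and -0.54. Of 7 posterior genes 6 were higher, Shh by construction among them, with Hoxd13 at 0.99 and 1.51 and Hand2 at 0.71 and 1.31. Of 10 BMP response genes 9 were higher, with medians of 0.87 and 0.55 (percentile 100 in both), among them Bambi (1.68 and 1.46) and Bmp7 (1.10 and 1.07). Of 9 FGF response genes 7 were higher, with Spry4 at 1.48 and 0.87 and Etv4 at 1.12 and 0.47. All 4 WNT response genes were higher, led by Lef1 (1.09 and 1.03). Of 9 ETS factors, a transcription factor family, 5 were higher and 3 lower, Ets2 at 0.82 and 0.91 and Erg at -1.28 and -0.80. Of 8 distal genes 5 were higher, Hoxa13 at 1.32 and 1.86. All 6 proximal genes were lower, with medians of -1.42 and -1.10 (percentile 0 in both), Meis1 at -2.65 and -1.77 and Meis2 at -2.66 and -1.63. All 4 anterior genes were lower, with medians of -0.62 and -0.79. Of 6 cartilage genes 4 were lower, Col9a1 at -2.18 and -1.90, and all 4 connective tissue genes were lower, Osr2 at -3.02 and -2.44. Of 8 mitosis genes 6 were higher, with medians of 0.15 and 0.13, and of 7 hypoxia genes 5, with medians of 0.07 and 0.15. Of 6 dissociation stress genes 4 were higher, Junb at 1.10 and 0.93. Lmbr1 was 0.69 and 0.78.

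The neighbours of the insertion site differed between the libraries. Eif4enif1, which encodes a protein that transports the cap-binding factor eIF4E, was 205 against 72.6 CPM in dual-enSERT-1, a 2.83-fold higher level in Shh-detected cells (2.71 to 2.96). In dual-enSERT-2 it was 57.3 against 56.2 CPM, 1.02-fold (0.924 to 1.12). Drg1, a GTP-binding protein gene, was 1.22-fold higher (1.16 to 1.28) and 1.04-fold (0.970 to 1.11). Eif4enif1 lies on chromosome 11 from 3152235 to 3194588 on the plus strand, within the span annotated for Drg1 on the minus strand, from 3137360 to 3216488. How strand was counted is not given in the sources used here, so reads of the pair cannot be separated with certainty.

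**Figure D4:**
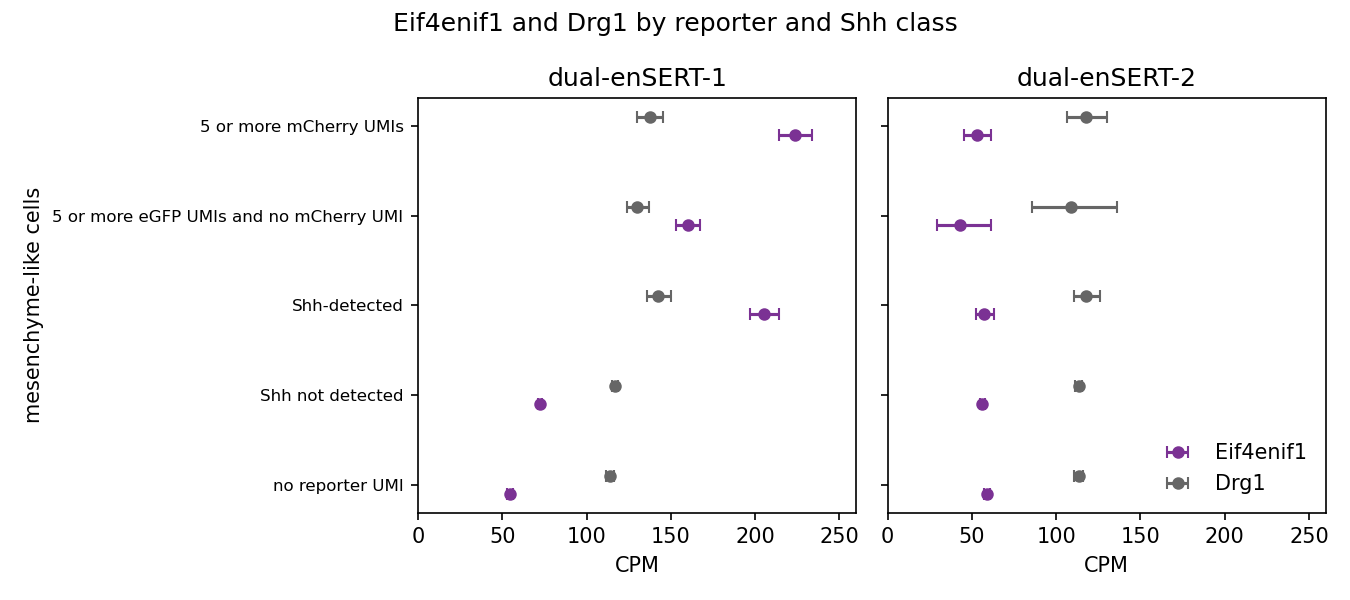
CPM of Eif4enif1 and Drg1, the annotated neighbours of the H11 insertion site, in classes of mesenchyme-like cells that overlap in part, with 95% Poisson intervals. In cells with 5 or more mCherry UMIs, Eif4enif1 stands at 224 CPM in dual-enSERT-1 and at 52.8 CPM in dual-enSERT-2.

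Between the libraries, mesenchyme-like cells of dual-enSERT-2 had less of both reporters, with log2 folds over dual-enSERT-1 of -2.39 for eGFP and -1.30 for mCherry, while Shh (0.08), Ptch1 (0.03) and Gli1 (0.22) were close. Lower in dual-enSERT-2 were Col2a1, the main collagen of cartilage (12.8 against 94.7 CPM, -2.79), Sulf1, a heparan sulfatase (-3.15), Wif1, a Wnt inhibitor (-3.09), Igfbp5, an IGF-binding protein (-2.90), and Fibin (-2.89). The chemokine Cxcl14 (-3.39), the transcription factors Tfap2b (-3.30) and Creb5 (-3.07), the protocadherin Pcdh10 (-2.98), the semaphorin receptor Nrp2 (37.0 against 286 CPM, -2.92), the phosphodiesterase Pde3a (-2.85) and 2700069I18Rik (-3.17) were lower as well. Higher in dual-enSERT-2 were Lin28a, an RNA-binding protein of early development (27.2 against 3.47 CPM, 2.65), Igdcc3 (281 against 58.0 CPM, 2.26), Styxl1 (2.84), Gm15564 (2.31) and the urokinase receptor Plaur (2.02). The other genes on this side were globins, Hbb-bs (4.50), Hbb-bh1 (4.14), Hba-x (3.69), Hbb-bt (3.48), Hba-a1 (3.40), Hbb-y (3.21) and Hba-a2 (2.92), in a library with 25.3% erythroid-like cells against 1.52%. Counts of the near-identical copies Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt, are uncertain.

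All 7 measured cartilage genes were lower in dual-enSERT-2, with a median of -1.78 (percentile 0), among them Sox6 (-2.55), Col9a3 (-2.47) and Sox9 (-1.42). The mesenchyme-like cells differed in make-up, as 5 clusters of dual-enSERT-1 had 502 to 930 CPM of Sox9 and no cluster of dual-enSERT-2 had more than 192 CPM. All 6 connective tissue genes were lower, with a median of -1.80 (percentile 0), among them Osr1 (-2.38), Osr2 (-2.30) and Scx (-1.80). Of 8 posterior genes 6 were lower, with Hoxd13 at -1.60, Hoxd12 at -1.35 and Hand2 at -0.43, and 5 of 7 anterior genes were higher, with Alx1 at 1.23 and Alx4 at 0.79. Of 9 FGF response genes 8 were higher, with a median of 0.55 (percentile 100), Dusp6 at 0.78 and Il17rd at 0.73. Of 9 distal genes 5 were higher and 4 lower, with Fgf10 at 0.84 and Hoxa13 at -1.62. Of 11 Shh response genes 6 were higher and 5 lower, with a median of 0.03 (percentile 72.3) and Bmp2 at -2.69. Of 6 proximal genes 4 were higher, with a median of 0.06. Medians were -0.27 for BMP response, -0.52 for WNT response, -0.09 for ETS factors, 0.22 for the hindlimb list, -0.21 for dissociation stress, -0.32 for hypoxia and 0.19 for mitosis, in which 7 of 8 genes were higher. The 4 measured sex-linked genes, Kdm5d (-0.25), Eif2s3y (-0.25), Uty (-0.26) and Ddx3y (-0.06, and 0.000424 as a mean over cells), were all Y-linked and present in both libraries, at 81.5 and 97.9 CPM for Uty. Both neighbours of the insertion site were lower in dual-enSERT-2, with a median of -0.27 (percentile 8.11). The median gene ratio between the libraries was -0.031 on the log2 scale. Drg1 stood at -0.06, Lmbr1 at -0.17 and Eif4enif1 at -0.49.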

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

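The 3 tests of the Xist pattern in this part were chosen only after the result was seen.

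With at least 20 CPM in either cell group and an absolute log2 fold of at least 0.58 in both libraries, 7 genes had opposite directions, each beyond its counting interval. Between anterior and posterior cells Nrk was 0.60 in dual-enSERT-1 and -0.96 in dual-enSERT-2 on the log2 scale. Between Shh-detected and other mesenchyme-like cells, Cyp26b1, which degrades retinoic acid, was 0.63 and -0.76, and the cartilage regulator Sox6 was -1.40 and 1.19. Sox6 was 50.1 and 45.7 CPM in Shh-detected cells and 134 and 19.4 CPM in the others, and 5 mesenchyme-like clusters of dual-enSERT-1 had 502 CPM or more of Sox9, against at most 192 CPM in those of dual-enSERT-2. The imprinted noncoding genes Meg3 and Rian, which lie in one locus, were -0.86 and 0.79 and -0.85 and 0.66. The sorting receptor gene Sorcs2 was -0.72 and 0.81, and the matrix gene Egflam -0.59 and 0.95. With 1 library per construct the difference was not tested for any of them.

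Reporter UMIs were also found in removed barcodes, in shallow unnamed clusters and in macrophage-like cells, which were part of the background named at the start. Barcodes of dual-enSERT-1 removed by the filter held 218 CPM of eGFP and 67.8 CPM of mCherry, and those of dual-enSERT-2 3.88 and 2.47 CPM. Shh in these barcodes was 5.03 CPM in dual-enSERT-1 and 15.5 CPM (12.4 to 19.1) in dual-enSERT-2, against 7.54 and 8.04 CPM in mesenchyme-like cells. A mesenchyme-like cluster of 125 cells in dual-enSERT-2 held 25.9 CPM of Shh, with 15.9 CPM of eGFP and 5.77 CPM of mCherry. The shallow unnamed cluster of dual-enSERT-1, in which Il31ra and Mir6236 stood out, held 359 CPM of eGFP and 113 CPM of mCherry, and the shallow clusters of dual-enSERT-2 17.6 and 14.7 CPM. Macrophage-like cells held 48.0 and 71.4 CPM of eGFP and 152 and 67.1 CPM of mCherry in dual-enSERT-1 and dual-enSERT-2, with 0 Shh UMIs where 29.1 and 35.3 would stand at the mesenchyme ratio of Shh to mCherry. A single cell of dual-enSERT-2 held 32 of the 94 mCherry UMIs. Without the highest cell of each library mCherry was 135 and 45.7 CPM (35.1 to 58.6), eGFP 48.9 and 58.3 CPM, and the Shh UMIs at that ratio 25.3 and 23.3. Macrophage-like cells also held the mesenchyme marker Prrx1, at 130 and 76.4 CPM against 779 and 752 CPM in mesenchyme-like cells. The source of their reporter UMIs was not tested.

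Xist, the RNA of the inactive X chromosome, was found in dual-enSERT-2, whose mesenchyme-like cells carried Y-linked transcripts. At least 3 Xist UMIs were counted in 32.2% of 1635 erythroid-like cells (29.9 to 34.5) and in 17.3% of 52 macrophage-like cells (8.23 to 30.3), and in 0 of 244 erythroid-like cells of dual-enSERT-1. Of the 526 erythroid-like cells with Xist, 13.1% (10.4 to 16.3) had a Y-linked UMI against 75.8% of the 1014 cells without Xist, which argues against free RNA or doublets as the whole source. Embryonic globins made up 83.9% of their globin UMIs, but also 71.5% in mesenchyme-like cells of this library with no Xist UMI. Free globin RNA could thus give a high share, and the globin level of the cells with Xist is not given. Blood of the mother therefore remains unsettled. At least 3 Xist UMIs were in 0.132% of mesenchyme-like cells (0.0429 to 0.308), which argues against limb tissue of a second, female embryo. Blood cells of a female littermate were not tested, and the design gives no biological explanation to test.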

How the results depend on the processing

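Inclusion of the shallow unnamed clusters and both subtractions of a background were tests chosen only after the data were seen; the other settings were fixed before. No paired analysis was possible because each group held 1 library. Each setting was run on the results it applies to. Over 14 settings and 32 results, 139 of 201 values stayed within the counting interval, 62 lay outside it and 0 turned direction. A turn could show only in the anterior to posterior ratios, the folds with Shh and the folds between libraries. Shares of cells and ratios of UMIs have no direction that could turn. Folds that could not be formed after subtraction of a background were left out. Over 11 settings and 199 gene folds, 953 of 1416 stayed, 456 moved and 7 turned direction. The gene folds carried the pseudocount but their intervals did not, so a low-level gene could count as moved though unchanged. Cck of dual-enSERT-1 was such a gene, and 456 is therefore not a count of changed folds. All 32 results stayed at resolution 0.5, and the 14 class shares stayed with at most 5% mitochondrial UMIs. Depth limits the shares of cells with a UMI and the split by Shh, and counting intervals cannot show how embryos vary. Except where stated, the cause was not tested.

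With at least 2000 genes, which removes shallow cells, dual-enSERT-1 was 91.0% mesenchyme-like, 2.17% ectoderm-like, 0.836% erythroid-like and 1.08% unnamed, and dual-enSERT-2 63.5% mesenchyme-like and 5.01% unnamed. With doublets kept, dual-enSERT-1 was 4.06% muscle-like, 1.83% erythroid-like and 8.22% unnamed, and its Shh-detected cells had 2.99-fold more eGFP and 18.6-fold more mCherry. Over all kept cells the folds with Shh were 3.36 for eGFP and 21.4 for mCherry in dual-enSERT-1 and 12.998 and 13.2 in dual-enSERT-2, where eGFP was detected in 6.04% and mCherry in 5.05%. As a mean of per-cell CPM the dual-enSERT-1 folds were 3.67 and 26.4, and the log2 fold of Ddx3y between libraries was 0.000424. With Shh detected at 2 UMIs the mCherry fold of dual-enSERT-1 was 20.7, and in dual-enSERT-2 eGFP was 12.4-fold and mCherry 13.9-fold higher.

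Without thinning, which leaves each cell its full depth, eGFP was detected in 47.2% and mCherry in 19.4% of dual-enSERT-1 mesenchyme-like cells, with 72.0% of eGFP-detected cells lacking mCherry. In dual-enSERT-2 these were 28.0%, 22.8% and 58.4%. The anterior to posterior ratios of dual-enSERT-1 were then 0.449 for eGFP and 0.134 for mCherry, and Cntn4 in eGFP-alone cells of dual-enSERT-2 was -0.013. With detection at 2 UMIs, a stricter call, the shares were 11.02%, 3.58% and 83.6% in dual-enSERT-1 and 1.89%, 1.73% and 70.4% in dual-enSERT-2. In eGFP-alone cells of dual-enSERT-2 Lsamp was then -0.51, Boc -0.013, Asb4 -0.095 and Hand2 0.033, and in dual-enSERT-1 Hoxd13 was 0.16. With the wider index gap the anterior to posterior ratio was 0.109 for mCherry in dual-enSERT-1 and 0.271 for eGFP in dual-enSERT-2, where mCherry, at 0.299 (0.129 to 0.590), stood above eGFP and not below it as in the main ranges. Median-ratio scaling put the fold between libraries at -2.36 for eGFP and -1.27 for mCherry.

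With the shallow unnamed clusters included, mesenchyme-like cells made up 90.7% and 68.3%, and the dual-enSERT-1 folds with Shh were 3.101 for eGFP and 21.0 for mCherry. With the background subtracted there were 2.49 and 1.46 eGFP UMIs per mCherry UMI. The anterior to posterior ratios were then 0.370 for eGFP and 0.0699 for mCherry in dual-enSERT-1 and 0.155 for eGFP in dual-enSERT-2. The folds with Shh were 4.02 for eGFP and 35.4 for mCherry in dual-enSERT-1 and 22.5 and 37.3 in dual-enSERT-2. Values after subtraction have no counting interval, and those with little reporter left are uncertain. No value was had for the anterior mCherry of dual-enSERT-2, which lay below this background. With endothelial-like cells left out of the background the ratio of UMIs was 2.48 in dual-enSERT-1. The anterior to posterior ratios were 0.367 for eGFP and 0.0691 for mCherry in dual-enSERT-1 and 0.235 and 0.142 in dual-enSERT-2, and the folds with Shh 4.04 and 35.5 in dual-enSERT-1 and 16.6 and 18.2 in dual-enSERT-2. Endothelial-like cells held 43 of the 69 mCherry UMIs of the dual-enSERT-2 background. Detection at 2 UMIs did not apply to the ratio of UMIs, the anterior to posterior ratios, the folds with Shh or the folds between libraries.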

Other observations

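The tests of free RNA, of distal cells, of Shh-expressing cells and of transcripts miscounted as Eif4enif1 were chosen only after the result was seen. The genes and lists of the first paragraphs were also chosen after their values were seen.

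The balance of the reporters shifted along the anterior-posterior index of dual-enSERT-1. There were 6.06 eGFP UMIs per mCherry UMI at an index of -1 (5.05 to 7.31), 4.57 at 0 (4.25 to 4.93), 3.19 at 1 (3.04 to 3.35), 2.66 at 2 (2.56 to 2.75), 2.23 at 3 (2.13 to 2.33) and 1.01 at 4 (0.928 to 1.11). At an index of -2 the ratio was 10.8 (5.83 to 22.3, 68 cells), but mCherry, at 9.83 CPM on 11 UMIs, was close to its background of 9.34 CPM. In dual-enSERT-2 the ratio followed no steady order, at 1.13 for an index of -2 (0.385 to 3.35, 24 cells), 1.64 at -1 (1.12 to 2.44), 1.54 at 0 (1.30 to 1.83), 1.204 at 1 (1.09 to 1.33), 1.26 at 2 (1.15 to 1.38), 1.40 at 3 (1.202 to 1.64) and 0.617 at 4 (0.447 to 0.846, 26 cells), and its mCherry at -1 and 0 was 0.880 and 0.911 times the background but 1.70 and 1.76 times that without endothelial-like cells. Within the middle range of dual-enSERT-1, distal cells held 156 CPM of eGFP and other cells 37.5 CPM, close to the background of 34.3 CPM.

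Other gene lists were read between cells with eGFP alone and mCherry-detected cells. Of 4 WNT response genes 3 were lower in both libraries, with medians of -0.21 and -0.23 (percentiles 0.08 and 0.17). Of 6 cartilage genes 3 were higher and 1 lower, with medians of 0.48 and 0.04 (percentiles 100 and 72.9), and of 9 FGF response genes 5 were lower, with medians of -0.19 and -0.01 (percentiles 0 and 41.2). Between Shh-detected and other cells, the Hedgehog co-receptor gene Cdon was lower in both libraries (-1.34 and -2.43), whereas the limb homeobox gene Lhx9 was 0.50 and -0.70. Celf2, an RNA-binding protein gene, was -0.10 and -1.36, and Rbfox3, a splicing regulator gene, 1.68 and 0.55.

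In dual-enSERT-1 the fold with Shh was 3.23 for eGFP and 22.6 for mCherry, while in dual-enSERT-2 they were 11.4 and 11.98. After subtraction of the background the eGFP fold of dual-enSERT-1 was 0.114 of the mCherry fold. That of dual-enSERT-2 was 0.602 of it (0.912 without endothelial-like cells in the background). Within distal cells of dual-enSERT-1 it was 0.140 before subtraction. These dual-enSERT-1 values argue against free RNA and against unequal shares of distal cells as the whole cause. With the background named at the start, mCherry of dual-enSERT-1 cells without Shh lay below background and no such fold could be formed there. Within distal cells the eGFP fold was then 0.0386 of the mCherry fold in dual-enSERT-1 and 0.926 of it in dual-enSERT-2. Over all mesenchyme-like cells of dual-enSERT-2 it was 0.716. The 0.0386 rests on 42.1 CPM of mCherry without Shh less a background of 32.1 CPM. Macrophage-like cells held 209 of the 390 mCherry UMIs of that background, so the 0.0386 carries little weight. Over 3 equal sets of the distal cells of dual-enSERT-1 without Shh, ordered by the 12 genes lower in dual-enSERT-2, the ratio was 5.59 eGFP UMIs per mCherry UMI (5.23 to 5.99) at a median of 158 CPM of these genes, 4.92 (4.68 to 5.18) at 539 and 5.19 (4.89 to 5.51) at 1126, so it did not rise with them. A later developmental state of dual-enSERT-1 still cannot be told apart, because the bound of 2 set beforehand for the lowest cells was wrong, as their 158 CPM lay above the 130 CPM of the dual-enSERT-2 cells with most, and the genes may order cells of 1 embryo by something other than its stage. The arrangement of the construct, which the design names, remains an untested explanation.

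Eif4enif1, beside the insertion site, had the largest excess of the dual-enSERT-1 over the dual-enSERT-2 fold with Shh among 6852 genes compared, at 2.83 against 1.02 (0.924 to 1.12), and the latter argues against a property of Shh-expressing cells whatever the construct. In distal cells of dual-enSERT-1 without Shh, Eif4enif1 was 3.11-fold higher (2.95 to 3.28) with 5 or more eGFP UMIs than with none, consistent with a hypothesis that an enhancer placed at H11 may also act on Eif4enif1. The same comparison in dual-enSERT-2 gave 0.639 (0.432 to 0.911, 26 cells). The 8 other genes compared within 500000 bp had a median log2 fold with Shh of 0.22 in dual-enSERT-1, the lowest gene at -0.35 and the highest at 0.63. Eif4enif1 excess with Shh was 0.00385 CPM per reporter CPM in dual-enSERT-2 (-0.0146 to 0.0238) against 0.159 in dual-enSERT-1, which argues against miscounted reporter sequence that both constructs hold. Transcripts of the dual-enSERT-1 construct alone counted as Eif4enif1 cannot be told apart from an enhancer acting on the gene, since the excess of 0.159 follows from either.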
